A study of Mus musculus with 173 samples.

How the data were processed

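Total RNA of lungs of BALB/c mice was labelled with an Affymetrix in vitro transcription kit and hybridised to expression arrays, 1 array per animal, and all samples had an RNA integrity number above 6, per the labels' protocols. The deposited values are log2 expression levels per probe set that were made with RMA, which corrects background, normalizes between arrays and summarises probes, per the submitters' processing notes. The version and settings of RMA are not given in the sources used here. The values ran from 2.95 to 15.43, and array medians from 9.20 to 9.37. The table held 25269 probe sets, and how these were selected is not given in the sources used here. The number of arrays limits the precision, and RMA values carry no read depth.

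Of the probe sets, 22127 were annotated to 1 gene, 256 to several and 2886 to none in the platform annotation used here. Probe sets with several genes or none were left out of the tests of named genes. Each gene was represented by the probe set with the highest mean over all arrays among those annotated to it alone, which gave 12918 genes, of which 5549 had more than 1 probe set. Of these genes 12874 had a gene identifier in the reference table, and 0 symbols needed updating. The range at the other probe sets is given for some named genes. Those that lost their call at another probe set are listed in the part on how the results depend on the processing.

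Samples were grouped by treatment and time from the labels into 24 groups of 6 to 8 animals. No pair of arrays held identical values. All groups entered 1 linear model with limma 3.58.1 in R 4.3.3, without covariates, and contrasts were moderated with eBayes (149 residual and 3.11 prior degrees of freedom, median residual SD 0.166). Infected animals were compared with vehicle animals within each of 10 times and vehicle with untreated animals within each of 4 times. F tests asked for an infection effect at any time, for a change of that effect between times and for variation among vehicle animals. Every limma p is two-sided and was adjusted with the Benjamini-Hochberg method within its comparison, with a threshold of 0.05. Comparisons of infected with vehicle lungs and of vehicle with untreated lungs share the vehicle arrays and are not set against each other.

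Before the data were examined, 43 gene lists (698 genes, 556 measured), a panel of 45 genes (34 measured), the tests and the alternatives were fixed. Lists were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison, and counts of members were also adjusted over the list alone. The text names, for each comparison, up to 8 genes with the largest rise and up to 5 with the largest fall past the threshold, leaving out clones and predicted genes. It also names up to 3 changed members of each list called by camera, genes of the panel, and the 5 genes with the largest F. Lists of liver, squamous epithelium and skeletal muscle genes were written after the data were seen. Their scores, and that of cardiac muscle, are mean log2 values per array. These scores and the actin difference given below were compared between infected and vehicle lungs with two-sided exact permutation tests, 50 in all, with Benjamini-Hochberg adjustment. RNA quality was measured as the difference between the 3' and 5' actin control probe sets, of which 3 were in the table. Gapdh control probe sets are not used here.

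The gene tests were tested on simulated data with 50 genes changed at each of 4 sizes. Values were drawn independently for each gene from a normal distribution with its residual SD, without correlation between genes or outlying arrays. The shares below describe that setting and need not hold for the real arrays. For the comparison at 7 d, 74% of genes changed 1.3-fold, 88% of those changed 1.5-fold and 100% of those changed 2-fold were recovered, and 9 of 190 calls were false. At 70 d the shares were 62%, 90% and 96%, with 7 of 181 calls false. At 4 d they were 80%, 92% and 98%, with 11 of 196 calls false.

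Alternatives covered the filter on dim genes, the normalization between arrays, the choice of probe set, the eBayes settings, array weights, RNA quality and residual components as covariates, the arrays entering the fit, a minimum fold of 1.5, the comparator and each array left out in turn. Leaving out arrays of doubtful RNA, adding scores of other tissues (for the log2 changes given with an SE as well as the counts) or a component of the clock genes as covariates, and repeating the list tests at 4 d without 1 array were added after the data were seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for permutation tests and figures.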

Results

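Gene expression was measured in whole lung of BALB/c mice after intranasal instillation of murine gammaherpesvirus MHV-68, a natural rodent relative of the human gammaherpesviruses that infects the lung and then persists in the host. Lungs of infected animals were compared with lungs of animals given vehicle at 10 times, from 2 h to 70 d, and untreated animals were sampled at 2 h, 6 h, 1 d and 4 d. The arrays hold 74 infected, 75 vehicle and 24 untreated animals, with 6 to 8 animals in each of the 24 groups of treatment and time. Each array came from 1 animal, and the labels give every array its own animal, so the spread between arrays includes the spread between animals. Array medians lay between 9.20 and 9.37 on the log2 scale. The number of arrays limits the precision, and the median standard error of a difference was 0.083 with 8 arrays a side and 0.096 with 6 a side. Changes below are log2 differences of group means with the standard error of the fit (SE), and a gene rose or fell only where its adjusted p was under 0.05. In whole lung a change in a gene list can come from the number of cells, from the level per cell or from both. Where a gene list is given a single camera adjusted p below 0.05, its call held with an estimated correlation between genes, and where it did not, the second p is given.

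The number of genes that differed between infected and vehicle lungs was 57 at 2 h, 216 at 6 h, 0 at 1 d and 132 at 4 d, of 12918 genes tested with limma. It reached 4770 at 7 d and 4845 at 14 d, and was 3312 at 21 d, 3215 at 35 d, 877 at 49 d and 146 at 70 d. At 1 d, 2149 genes had an unadjusted p under 0.05. With a fold of at least 1.5 required as well, 661 genes passed at 7 d, 938 at 14 d, 741 at 21 d, 414 at 35 d, 191 at 49 d and 77 at 70 d. Vehicle and untreated lungs differed in 451 genes at 2 h, 9 at 6 h, 110 at 1 d and 0 at 4 d, where 721 had an unadjusted p under 0.05.

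**Figure D1:**
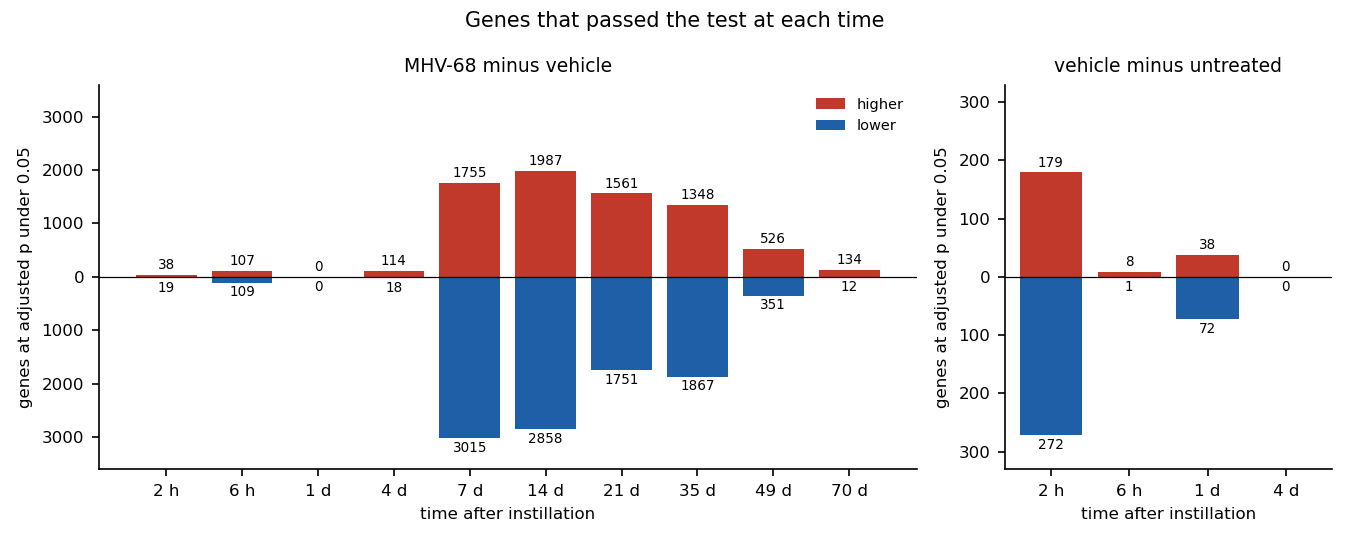
Bars show the number of genes higher (above 0) or lower (below 0) at adjusted p under 0.05 at each time, for infected minus vehicle lungs (left) and vehicle minus untreated lungs (right, with a finer vertical scale). The counts are largest at 7 d, with 1755 genes higher and 3015 lower, and at 14 d, with 1987 higher and 2858 lower. A fold of at least 1.5, not required in the bars, leaves 487 higher and 174 lower at 7 d and 684 and 254 at 14 d.

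The comparison at 2 h asks what had changed in the lung within hours of receiving the virus (n = 6 infected and 6 vehicle). Saa3, an acute phase protein, rose by 1.31 ± 0.29 (SE), a fold of 2.49, and Slc26a4, an anion exchanger of the airway epithelium, rose by 1.24 ± 0.23. Each was higher in 6 of 6 infected lungs than in any vehicle lung. Padi4, a protein-citrullinating enzyme of neutrophils, rose by 0.73 ± 0.18, and Ccr2, a chemokine receptor of monocytes, by 0.60 ± 0.15. Of the 57 genes, 38 were higher and 19 lower, among the latter Zmat4 (fell by 1.15 ± 0.27) and Arhgap28 (fell by 0.66 ± 0.11). Against untreated lungs Zmat4 and Arhgap28 were at -0.65 and -0.30 and did not pass. The calls of Padi4, Ccr2 and Zmat4 each ended without some single arrays, 8, 7 and 3 of the 12. None of the 13 measured neutrophil genes passed over all genes in the limma test, and 7 rose when adjusted over the list alone (camera adjusted p = 2.54e-08, and adjusted p = 0.47 with an estimated correlation). Of 20 inflammatory cytokine and chemokine genes 1 rose, and 5 did when adjusted over the list alone (camera adjusted p = 4.74e-06, and adjusted p = 0.523 with an estimated correlation). Of 19 genes of monocytes and recruited macrophages 1 rose, Ccr2, and 4 did when adjusted over the list alone (camera adjusted p = 1.31e-05, and adjusted p = 0.523 with an estimated correlation). The count of 57 genes fell to 2 when only the arrays of the 2 groups entered the fit and was 95 without arrays of doubtful RNA. It also depended on single arrays, being 22 without MHV_2h replicate 5, 24 without MHV_2h replicate 1, 36, 31 and 32 without Control_Prep_2h replicates 1, 5 and 6.

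At 6 h (n = 8 and 8), 107 genes were higher and 109 lower in infected lungs, or 47 and 4 with a fold of at least 1.5 as well. Chemokine and inflammatory genes were among those that rose: the neutrophil chemokine Cxcl3 by 1.31 ± 0.34, Acod1, the enzyme that makes itaconate in macrophages, by 1.21 ± 0.31, and Cxcl1 by 0.94 ± 0.26. The interferon-stimulated genes Ifit1 and Rsad2 rose by 0.59 ± 0.13 and 0.58 ± 0.15. The endothelial genes Pecam1, Tie1 and Kdr fell by 0.50 ± 0.14, 0.40 ± 0.11 and 0.29 ± 0.08, and Il22ra2, a soluble receptor that binds interleukin 22, fell by 0.95 ± 0.18. Asb5 and Klhl41, genes of skeletal muscle, rose by 1.53 ± 0.42 and 1.27 ± 0.37, and Cdsn and Sprr1a, genes of squamous epithelium, by 1.19 ± 0.31 and 1.19 ± 0.34. Scores of lists of such genes, written after the data were seen, varied widely between arrays of every treatment at 2 h and 6 h. At 6 h the squamous score was 9.46 ± 2.49 (SD) in infected and 8.24 ± 2.52 in vehicle lungs, an exact permutation p of 0.347. The skeletal muscle score was 9.98 ± 2.77 and 9.21 ± 2.38, an exact permutation p of 0.539. With scores of other tissues as covariates Klhl41, Cdsn and Sprr1a were at 0.56, 0.63 and 0.70 and did not pass, nor did Cxcl1, Pecam1, Tie1 and Kdr at 0.94, -0.46, -0.40 and -0.26. Asb5 still passed with them, at 0.86 (limma adjusted p = 0.00966).

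Of the 13 genes given with an SE at 6 h, 8 did not pass against untreated lungs: Il22ra2 (-0.24), Pecam1 (-0.27), Tie1 (-0.18), Kdr (-0.23), Asb5 (0.88), Klhl41 (0.67), Cdsn (0.83) and Sprr1a (0.87). The chemokine genes Cxcl3 and Cxcl1 were 4.83 and 2.13 above untreated lungs. Without MHV_6h replicate 2, Asb5 and Klhl41 were at 1.01 and 0.82 (limma adjusted p = 0.454 and 0.5), and Pecam1, Tie1 and Kdr at -0.18, -0.19 and -0.12, none of which passed, nor did Sprr1a at 1.40. The other 7 passed without it, Cxcl3, Acod1, Cxcl1 and Cdsn at 1.75, 1.55, 1.15 and 1.35, and Ifit1, Rsad2 and Il22ra2 at 0.58, 0.67 and -0.81. The calls of 11 of the 13 genes ended when some single array was left out, those of Ifit1 and Il22ra2 being the exceptions. Saa3, Cxcl5, Ccl20 and Tnfrsf9, singled out after their values were seen, also rose at 6 h, by 1.16, 0.90, 0.86 and 0.83. They passed without MHV_6h replicate 2, at 1.23, 0.92, 0.91 and 1.02, and with scores of other tissues, at 1.13, 0.86, 0.79 and 0.92. Most of the genes called at 6 h did not pass without that array.

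By list, 5 of 20 inflammatory genes rose at 6 h (7 adjusted over the list alone, camera adjusted p = 1.51e-07, and adjusted p = 0.469 with an estimated correlation). Of 16 endothelial genes 6 fell (13 adjusted over the list alone, camera adjusted p = 1.68e-09, and adjusted p = 0.469 with an estimated correlation). Of 30 genes stimulated by type I interferon 2 rose (3 adjusted over the list alone, camera adjusted p = 0.00997, and adjusted p = 0.678 with an estimated correlation). Of the 216 genes, 18 passed in the same direction without MHV_6h replicate 2, and 20 passed in all. That array also had the largest 3' to 5' actin difference of its group (2.07, against at most 1.38 in the others). The count lay between that 20 and 861, without MHV_6h replicate 3, when single arrays were left out, and was 1 when only the arrays of these groups were fitted and 55 with scores of other tissues as covariates.

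No gene passed in the limma test at 1 d (n = 7 and 8), and no list call held with an estimated correlation. The 6 lists called with the preset correlation included immediate early genes, of which 3 of 17 rose when adjusted over the list alone (camera adjusted p = 8.96e-06, and adjusted p = 0.803 with an estimated correlation). Saa3 was 1.23 ± 0.26 above vehicle and did not pass (limma adjusted p = 0.0842), with 5 of 7 infected lungs above any vehicle lung. Against untreated lungs Saa3 was at 2.51 and passed (limma adjusted p = 2.42e-11). Irf7 differed from vehicle by 0.05 ± 0.15 (limma adjusted p = 0.866). The count at 1 d was 23 without MHV_1d replicate 1, 15 without Control_Prep_1d replicate 4, 151 without arrays of doubtful RNA and 1432 with array weights.

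At 4 d (n = 8 and 8) the infected lungs differed from vehicle lungs in 114 genes that were higher and 18 that were lower, and genes stimulated by interferon led the rises. Cxcl10, a chemokine that draws activated T cells, rose by 2.23 ± 0.23, a fold of 4.70, and the antiviral genes Mx1, Mx2, Oasl1 and Ifit1 rose by 1.84 ± 0.21, 1.75 ± 0.14, 1.63 ± 0.16 and 1.62 ± 0.13. Irf7, which amplifies type I interferon production, rose by 1.58 ± 0.14 and was higher in 7 of 8 infected lungs than in any vehicle lung. Of 30 measured genes stimulated by type I interferon 29 rose and 1 did not pass (30 adjusted over the list alone, camera adjusted p = 6.33e-197). Of 21 genes induced by interferon gamma 13 rose (17 adjusted over the list alone, camera adjusted p = 1.38e-43), among them Cxcl9 by 1.34 ± 0.34 and Iigp1 by 1.25 ± 0.20. MHC class I presentation genes rose in 4 of 12 cases (8 adjusted over the list alone, camera adjusted p = 1.3e-11), led by the peptide transporter Tap1 at 0.54 ± 0.12 (0.04 at its second probe set and 0.41 against untreated lungs, neither of which passed). The call of Cxcl9 ended without any of 5 single arrays of the 16. The chemokine Ccl12 and Saa3 rose by 1.23 ± 0.26 and 1.17 ± 0.25. They were the 2 of 20 inflammatory genes that passed, and also the 2 adjusted over the list alone (camera adjusted p = 0.0138, and adjusted p = 0.796 with an estimated correlation).

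Clock genes changed as well at 4 d. The activators Npas2 and Arntl fell by 0.86 ± 0.20 and 0.68 ± 0.17, and Hlf, Per3 and Tef rose by 0.47 ± 0.11, 0.38 ± 0.11 and 0.32 ± 0.09. Per3 did not pass with quantile normalization or median centring, nor did Tef with median centring, and the second probe set of Npas2 gave -0.20 and did not pass. The calls of Per3, Tef, Arntl and Hlf ended without some single arrays, 10, 8, 5 and 1 of the 16. Per3 and Tef were at 0.31 and 0.23 against untreated lungs and at 0.37 and 0.30 with scores of other tissues as covariates, and did not pass. Of 16 clock genes 3 rose, 2 fell and 11 did not pass (9 up and 2 down adjusted over the list alone, camera adjusted p = 0.000131 and adjusted p = 0.0296 with an estimated correlation). The time of day at which animals were killed is not given in the sources used here. None of 14 B cell genes passed over all genes in the limma test, and 8 fell adjusted over the list alone (camera adjusted p = 5.21e-10, and adjusted p = 0.174 with an estimated correlation). MHV_4d replicate 5 stood apart from its group, with a Cxcl10 value of 7.97 against 10.12 to 11.97 in the other 7 infected lungs and 8.16 to 9.05 in vehicle lungs. Without it the B cell list had a camera adjusted p = 0.000326, and adjusted p = 0.667 with an estimated correlation. The clock list had a camera adjusted p = 0.000886, and adjusted p = 0.0941 with an estimated correlation. The count of 132 genes lay between 106 and 144 when any 1 array was left out and was 47 when only the arrays of these groups were fitted.

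At 7 d (n = 8 and 8), 36.9% of the genes tested differed, 1755 higher and 3015 lower. The balance was reversed among genes that also had a fold of at least 1.5, with 487 higher and 174 lower. The median change of all genes tested was -0.055. Genes induced by interferon gamma were among the largest rises: Cxcl9 by 6.26 ± 0.34 (a fold of 76.8, and 4.40 at its second probe set), Cxcl11 by 4.93 ± 0.17, Ubd by 4.84 ± 0.30, Cxcl10 by 4.78 ± 0.23 and the tryptophan-degrading enzyme Ido1 by 3.97 ± 0.22. Ifng itself rose by 3.56 ± 0.19, a fold of 11.8, and was higher in 8 of 8 infected lungs than in any vehicle lung. The granzymes Gzmb and Gzmk, effector proteases of cytotoxic lymphocytes, rose by 2.62 ± 0.23 and 2.05 ± 0.20. The acute phase and inflammatory genes Saa3, Ccl12 and Il6 rose by 4.00 ± 0.25, 3.52 ± 0.26 and 3.15 ± 0.35, and the complement genes Cfb and C1qc by 1.98 ± 0.12 and 1.31 ± 0.10. Among the falls were the B cell genes Cr2, Fcrla and Blk (by 1.17 ± 0.19, 1.15 ± 0.20 and 1.08 ± 0.18), the immunoglobulin A gene Igha (by 1.3 ± 0.36), the fatty acid binding protein Fabp1 (by 1.54 ± 0.25) and the lectin Cd209f (by 1.36 ± 0.19).

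Every one of 30 type I interferon genes (30 adjusted over the list alone) and 21 interferon gamma genes (21 adjusted over the list alone) rose at 7 d, with camera adjusted p of 8.23e-82 and 3.31e-69. All 12 genes of MHC class I presentation rose (12 adjusted over the list alone, camera adjusted p = 1.82e-26), as did 17 of 20 inflammatory genes (17 adjusted over the list alone, camera adjusted p = 1.74e-23). Of 25 cell cycle genes 23 rose (24 adjusted over the list alone, camera adjusted p = 9.1e-20), including Hmmr by 1.43 ± 0.19 and Mcm5 by 1.13 ± 0.13. Of 10 T cell checkpoint genes 9 rose (9 adjusted over the list alone, camera adjusted p = 2.86e-13), led by Tnfrsf9 at 2.06 ± 0.14, Ctla4 at 1.81 ± 0.17 and Pdcd1 at 1.33 ± 0.15. Of 19 genes of monocytes and recruited macrophages 13 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 3.11e-12), with the Fc receptors Fcgr1 and Fcgr4 up by 2.09 ± 0.19 and 2.05 ± 0.20. Complement genes rose in 7 and fell in 1 of 11 cases (7 and 1 adjusted over the list alone, camera adjusted p = 9.35e-09).

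Cytotoxic effector genes rose in 17 of 20 cases at 7 d (17 up and 1 down adjusted over the list alone, camera adjusted p = 1.3e-12, and adjusted p = 0.102 with an estimated correlation). Of 15 T cell genes 10 rose (10 adjusted over the list alone, camera adjusted p = 3.21e-05, and adjusted p = 0.349 with an estimated correlation). Of 14 B cell genes 13 fell and 1 rose (13 and 1 adjusted over the list alone, camera adjusted p = 5.03e-05, and adjusted p = 0.349 with an estimated correlation). Genes of ciliated epithelium fell in 10 of 18 cases (10 adjusted over the list alone, camera adjusted p = 0.0217, and adjusted p = 0.849 with an estimated correlation), and their dynein gene Dnaic1 fell by 0.67 ± 0.17. Endothelial genes fell in 7 of 16 cases (8 adjusted over the list alone, camera adjusted p = 0.0262, and adjusted p = 0.788 with an estimated correlation). In the alternative activation list the largest rises were those of Clca1, a goblet cell product, and the chemokines Ccl8 and Ccl11, by 3.20 ± 0.52, 2.92 ± 0.21 and 1.28 ± 0.15. Of the 13 genes of that list 6 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.00113, and adjusted p = 0.104 with an estimated correlation). The count of 4770 lay between 4170 and 4940 when any 1 array was left out.

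**Figure D2:**
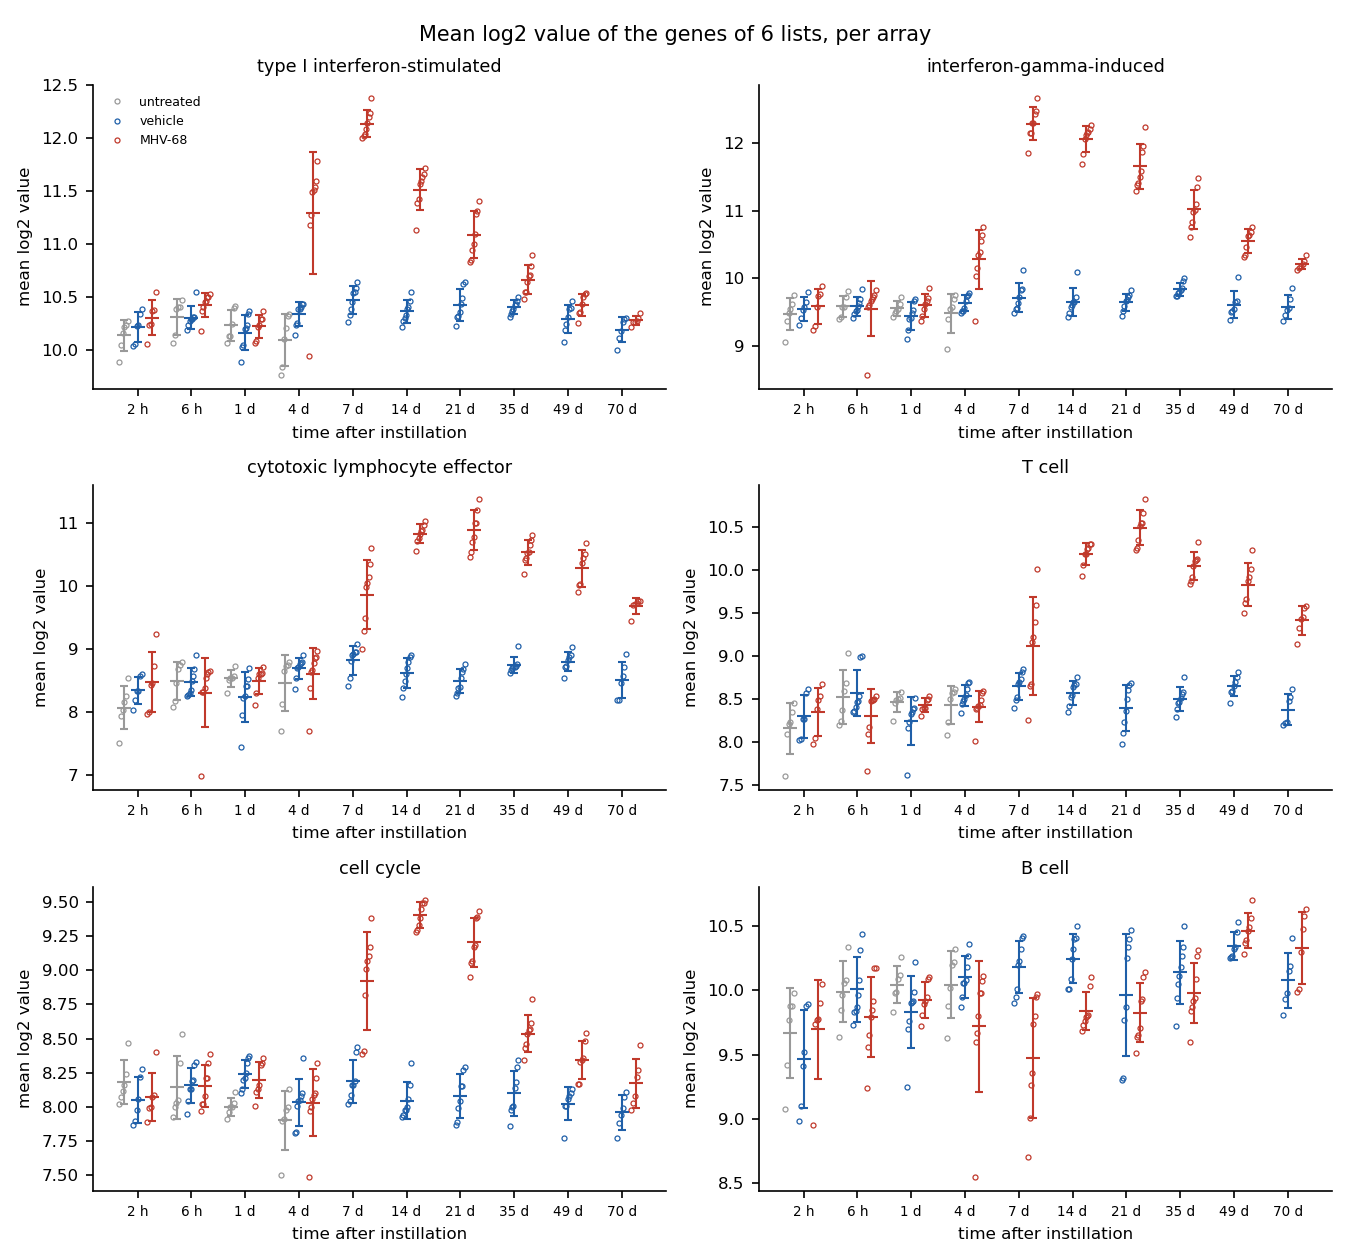
Each point is the mean log2 value of a list's genes on 1 array, at each time after instillation, for untreated, vehicle and infected lungs; bars show the group mean and SD. Genes stimulated by type I interferon stand highest in infected lungs at 7 d, and the T cell genes remain above the vehicle lungs through 70 d, where 15 of 15 passed the test.

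At 14 d (n = 8 and 8), 1987 genes were higher and 2858 lower, or 684 and 254 with a fold of at least 1.5 as well. Lymphocyte genes stood beside the interferon gamma genes among the largest rises. Gzmk rose by 5.09 ± 0.20, a fold of 34.1, Gzmb by 3.58 ± 0.23, Ifng by 3.69 ± 0.19 and Cd8a, a coreceptor of cytotoxic T cells, by 2.82 ± 0.20. The inhibitory receptor gene Pdcd1 rose by 2.85 ± 0.15 and the homing receptor gene Cxcr6 by 2.78 ± 0.15. Cxcl9, Ubd, Acod1 and Ido1 rose by 6.21 ± 0.34, 4.94 ± 0.30, 4.70 ± 0.31 and 4.05 ± 0.22. Ighm, the immunoglobulin M heavy chain, rose by 6.03 ± 0.57 at its main probe set and and gave 0.84 to 1.16 at its other 4, none of which passed, so its size is uncertain. The macrophage genes Ms4a7 and Gpnmb rose by 2.87 ± 0.14 and 2.34 ± 0.11. Slc5a12, a lactate transporter, fell by 2.25 ± 0.23 and was lower in 8 of 8 infected lungs than in any vehicle lung, and Esm1, an endothelial proteoglycan, fell by 1.90 ± 0.20.

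At 14 d 25 of 25 cell cycle genes also rose (25 adjusted over the list alone, camera adjusted p = 5.06e-43), with Hmmr, Kif11 and Cdk1 up by 2.27 ± 0.19, 1.99 ± 0.13 and 1.90 ± 0.13. All 15 T cell genes rose (15 adjusted over the list alone, camera adjusted p = 1.29e-28), as did 19 of 20 cytotoxic effector genes (20 adjusted over the list alone, camera adjusted p = 8.86e-36). Natural killer cell genes rose in 8 of 9 cases (9 adjusted over the list alone, camera adjusted p = 2.19e-08) and checkpoint genes in 10 of 10 (10 adjusted over the list alone, camera adjusted p = 3.4e-18). All 21 interferon gamma genes (21 adjusted over the list alone, camera adjusted p = 1.52e-53) and all 30 type I interferon genes (30 adjusted over the list alone, camera adjusted p = 4.85e-37) rose. Genes of monocytes and recruited macrophages rose in 17 of 19 cases (17 adjusted over the list alone, camera adjusted p = 3.41e-25). Dendritic cell genes rose in 7 and fell in 1 of 13 (7 and 2 adjusted over the list alone, camera adjusted p = 6.42e-06), with Xcr1 and Itgae up by 1.58 ± 0.10 and 1.41 ± 0.10.

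Matrix genes rose in 12 and fell in 2 of 20 cases at 14 d (13 and 3 adjusted over the list alone, camera adjusted p = 0.00378, and adjusted p = 0.313 with an estimated correlation). Among them Mmp12, Eln and Tnc rose by 0.99 ± 0.17, 0.97 ± 0.12 and 0.93 ± 0.17. Xenobiotic metabolism genes fell in 11 and rose in 1 of 18 cases (14 and 1 adjusted over the list alone, camera adjusted p = 0.00106, and adjusted p = 0.065 with an estimated correlation). Cyp1a1 fell by 1.16 ± 0.23 and Ces1g by 0.88 ± 0.14. Ciliated epithelium genes fell in 12 of 18 cases (14 adjusted over the list alone, camera adjusted p = 0.00319, and adjusted p = 0.646 with an estimated correlation). Smooth muscle genes fell in 7 of 10 cases (9 adjusted over the list alone, camera adjusted p = 0.015, and adjusted p = 0.415 with an estimated correlation). Club and secretory cell genes fell in 11 of 18 cases (11 down and 1 up adjusted over the list alone, camera adjusted p = 0.0443, and adjusted p = 0.646 with an estimated correlation). The club cell product Scgb1a1 fell by 0.06 ± 0.03, the only time it passed, and it did not pass with quantile normalization, with median centring, with scores of other tissues or without any of 9 single arrays of the 16. The actin 3' to 5' difference, a measure of RNA quality, was 0.96 ± 0.16 (SD) in infected and 1.22 ± 0.10 in vehicle lungs at 14 d, an exact permutation p of 0.00155 and adjusted p of 0.0258 over 50 such tests. With it as a covariate the count of 4845 stayed within 1.5 times.

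**Figure D3:**
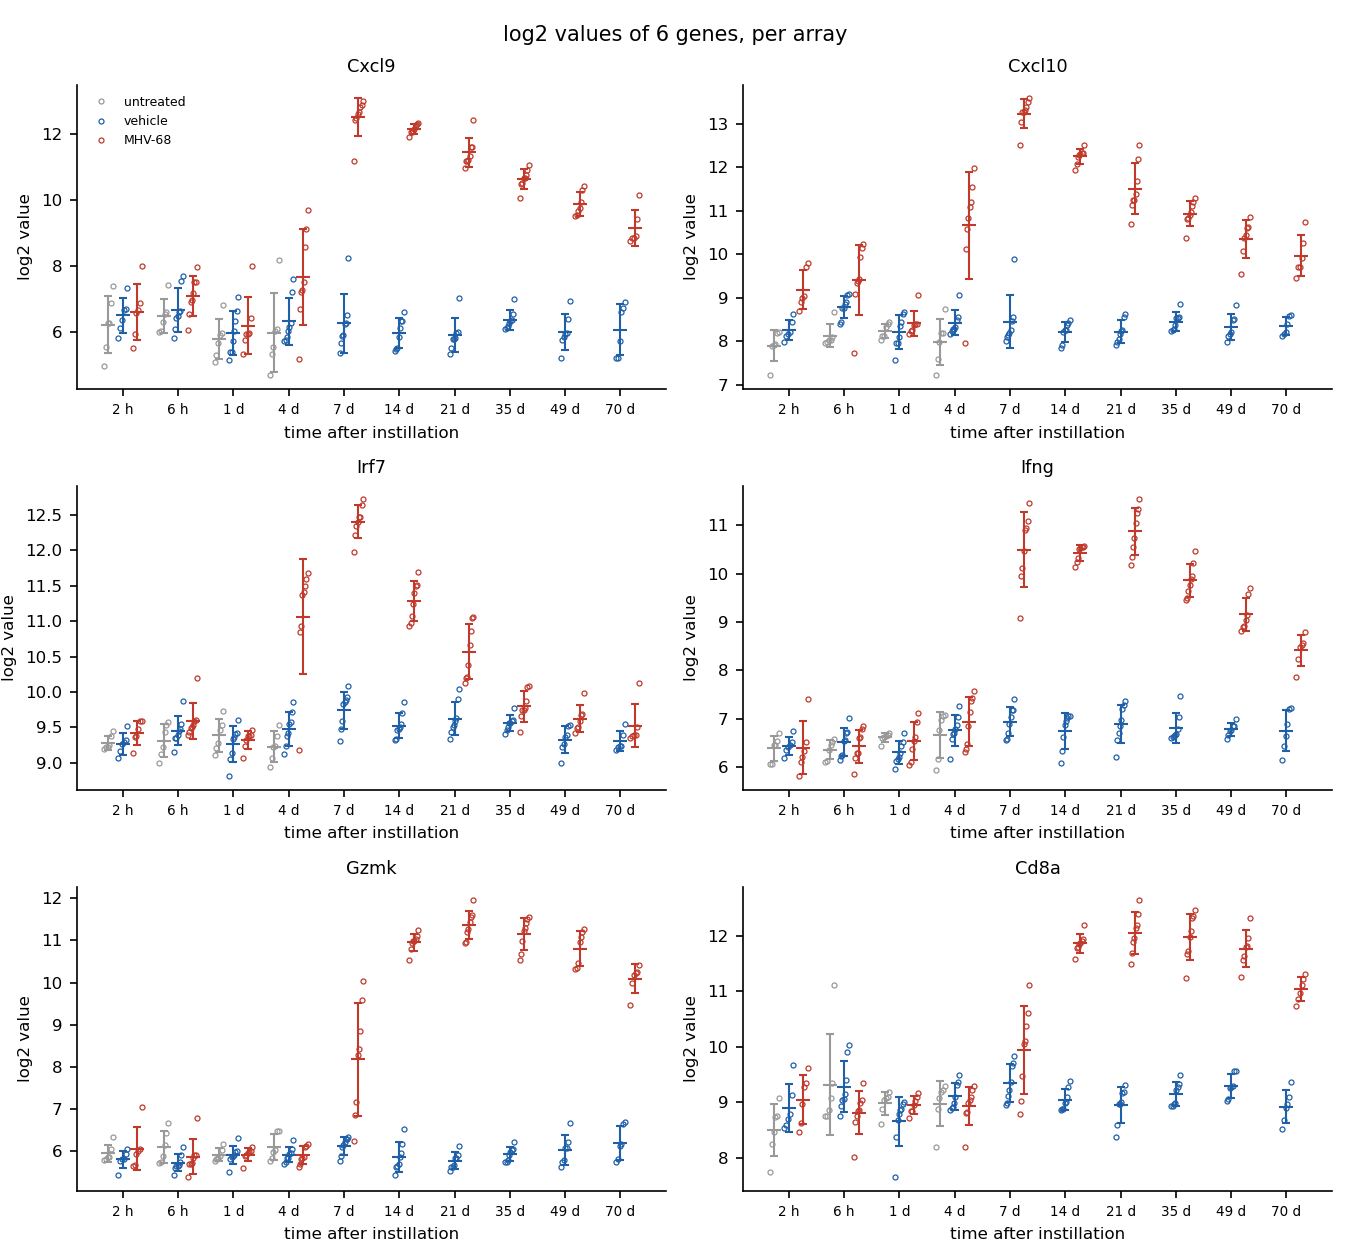
Points are log2 values of single arrays for Cxcl9, Cxcl10, Irf7, Ifng, Gzmk and Cd8a at each time after instillation, with the group mean and SD, for untreated, vehicle and infected lungs. Gzmk in infected lungs is above all vehicle lungs in 8 of 8 arrays at 14 d and in 6 of 6 at 70 d.

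At 21 d (n = 8 and 8), 1561 genes were higher and 1751 lower, or 576 and 165 with a fold of at least 1.5 as well. Gzmk rose by 5.6 ± 0.20, a fold of 48.4, Cxcl9 by 5.55 ± 0.34, Ubd by 4.56 ± 0.30, Ifng by 3.99 ± 0.19 and Klrg1, a receptor of differentiated effector lymphocytes, by 3.37 ± 0.17. Cd8a and Cd4, the coreceptors of the main T cell classes, rose by 3.10 ± 0.20 and 1.89 ± 0.11. All 15 T cell genes rose (15 adjusted over the list alone, camera adjusted p = 6.1e-52), as did 18 of 20 cytotoxic effector genes (18 adjusted over the list alone, camera adjusted p = 4.79e-49). So did 20 of 21 interferon gamma genes (21 adjusted over the list alone, camera adjusted p = 3.77e-52), 25 of 25 cell cycle genes (25 adjusted over the list alone, camera adjusted p = 1.04e-40) and 25 of 30 type I interferon genes (26 adjusted over the list alone, camera adjusted p = 6.9e-19). Genes of MHC class II presentation rose in 7 of 9 cases (8 adjusted over the list alone, camera adjusted p = 3.67e-11), and the class II transactivator Ciita rose by 1.51 ± 0.13. Xenobiotic metabolism genes fell in 12 and rose in 1 of 18 cases (13 and 1 adjusted over the list alone, camera adjusted p = 0.000109). Cyp1a1 fell by 1.78 ± 0.23, and the secretory gene Bpifa1 fell by 1.43 ± 0.40.

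Club and secretory cell genes fell in 11 of 18 cases at 21 d (11 adjusted over the list alone, camera adjusted p = 0.00092, and adjusted p = 0.318 with an estimated correlation). In the thymus list 1 of 3 genes rose, Themis, a signalling protein of T cells, by 2.84 ± 0.18 (1 adjusted over the list alone, camera adjusted p = 0.0077, and adjusted p = 0.105 with an estimated correlation). Cardiac muscle genes fell in 8 of 15 cases (11 adjusted over the list alone, camera adjusted p = 0.00277, and adjusted p = 0.596 with an estimated correlation). The cardiac score was 10.51 ± 0.35 (SD) in infected and 11.06 ± 0.31 in vehicle lungs, an exact permutation p of 0.00326 and adjusted p of 0.0326. The liver score ranged up to 11.36 in infected and 11.05 in vehicle lungs at 21 d, with an exact permutation p of 0.737 between treatments. The count of 3312 was 2161 without the third of genes of lowest mean.

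At 35 d (n = 8 and 8), 1348 genes were higher and 1867 lower, or 280 and 134 with a fold of at least 1.5 as well. The rises were again in cytotoxic and interferon gamma genes: Gzmk by 5.22 ± 0.20, a fold of 37.4, Cxcl9 by 4.29 ± 0.34, Ubd by 3.37 ± 0.30, Cd8b1 by 3.06 ± 0.25, Ifng by 3.05 ± 0.19 and Klrg1 by 2.88 ± 0.17. All 15 T cell genes rose (15 adjusted over the list alone, camera adjusted p = 5.38e-50). So did 17 of 20 cytotoxic effector genes (17 up and 1 down adjusted over the list alone, camera adjusted p = 4.64e-47) and 19 of 21 interferon gamma genes (19 adjusted over the list alone, camera adjusted p = 8.44e-32). Of 30 type I interferon genes 12 rose (13 adjusted over the list alone, camera adjusted p = 1.62e-06, and adjusted p = 0.408 with an estimated correlation). Of 25 cell cycle genes 18 rose (20 adjusted over the list alone, camera adjusted p = 7.13e-13, and adjusted p = 0.0751 with an estimated correlation). The 5 largest falls were genes of hepatocytes: Cps1, a urea cycle enzyme, fell by 4.18 ± 0.61 and Serpina1c fell by 3.70 ± 0.67. Cyp3a11 fell by 3.43 ± 0.71, Mug1 fell by 3.43 ± 0.53 and Ugt2b1 fell by 3.34 ± 0.46.

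The liver score was 6.86 ± 0.76 (SD) in infected and 9.86 ± 1.13 in vehicle lungs at 35 d, an exact permutation p of 0.000155 and adjusted p of 0.00775. The vehicle median of this score was 5.51 at 14 d, 7.20 at 21 d, 5.64 at 49 d and 5.55 at 70 d. The liver list was written after the data were seen, and 4 of its 12 genes, Cps1, Serpina1c, Mug1 and Cyp3a11, are among the largest falls above, so this p is not independent evidence of its direction. The cardiac score was 10.63 ± 0.20 and 11.08 ± 0.22, an exact permutation p of 0.00155 and adjusted p of 0.0258. Secretory genes of the airway fell too: Bpifa1 fell by 2.4 ± 0.40, Bpifb1 fell by 1.18 ± 0.28 and Scgb3a1 fell by 0.68 ± 0.23. Bpifb1 also varied strongly between times among vehicle lungs alone (limma F = 31.9), and the reason was not tested. Of 18 club and secretory cell genes 5 fell (5 adjusted over the list alone, camera adjusted p = 0.0205, and adjusted p = 0.64 with an estimated correlation). With scores of liver, squamous epithelium, skeletal and cardiac muscle as covariates 2342 genes passed, 1967 of them among the 3215 and in the same direction. With them Cps1 and Ugt2b1 were at -0.17 and -0.31, Mug1 at 0.1 and Scgb3a1 at -0.45, and none of these passed, while Cyp3a11 and Serpina1c passed the other way at 1.18 and 0.77. The liver score holds Cps1, Mug1, Cyp3a11 and Serpina1c themselves. When only the arrays of these groups were fitted, 5430 genes passed.

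**Figure D4:**
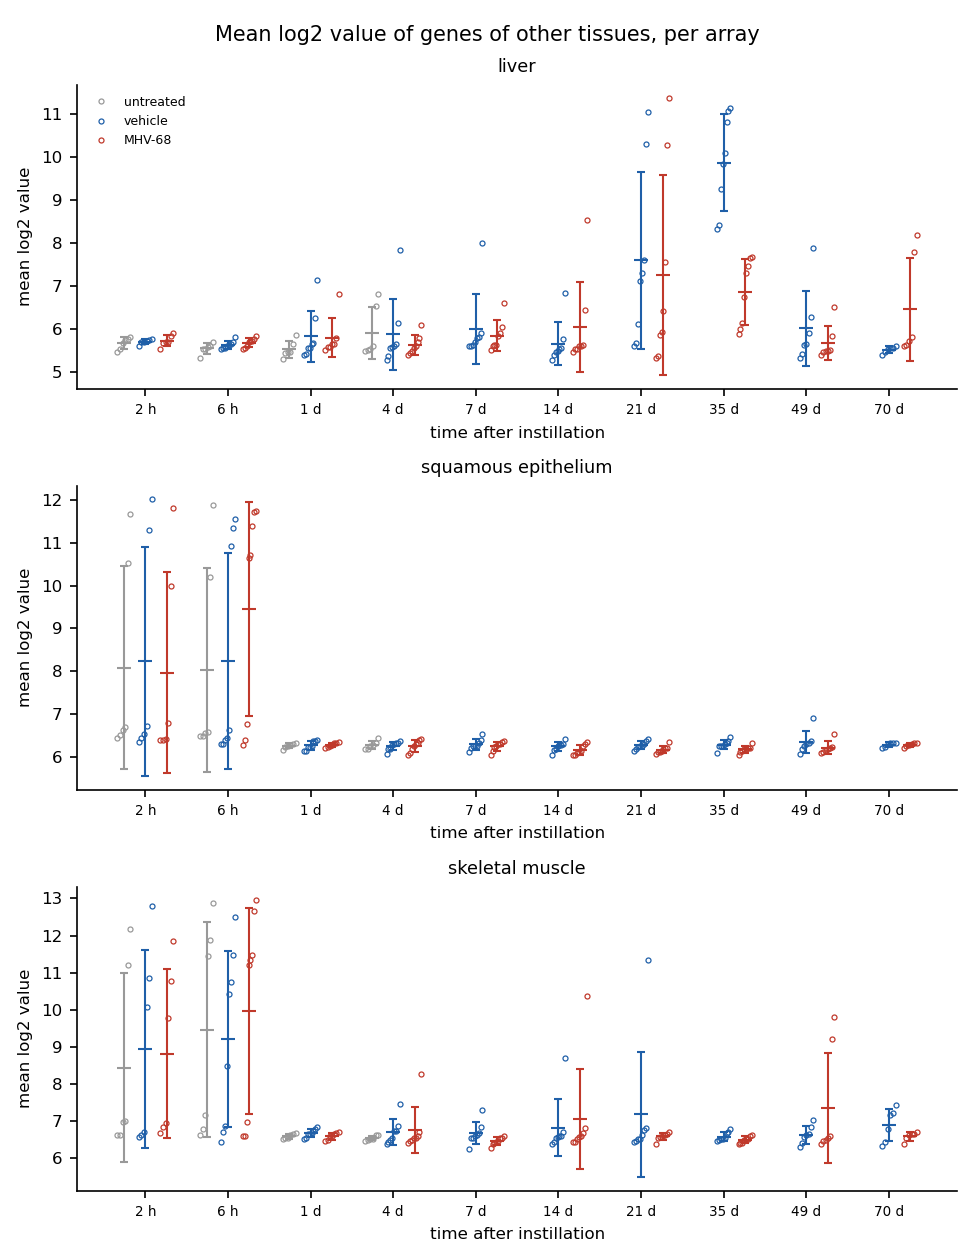
Points are the mean log2 values, on single arrays, of genes of liver, squamous epithelium and skeletal muscle at each time after instillation, with the group mean and SD, for untreated, vehicle and infected lungs. The liver score of vehicle lungs at 35 d runs from 8.31 to 11.14 and that of infected lungs from 5.89 to 7.68, and the squamous and skeletal muscle scores of some arrays of every treatment are high at 2 h and 6 h.

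At 49 d (n = 7 and 7), 526 genes were higher and 351 lower. Gzmk rose by 4.78 ± 0.22, a fold of 27.6, Cxcl9 by 3.88 ± 0.37, Klrg1 by 2.64 ± 0.19, Cd8b1 by 2.54 ± 0.26 and Ifng by 2.38 ± 0.20. All 15 T cell genes rose (15 adjusted over the list alone, camera adjusted p = 1.27e-54), as did 17 of 20 cytotoxic effector genes (18 adjusted over the list alone, camera adjusted p = 1.1e-56) and 17 of 21 interferon gamma genes (19 adjusted over the list alone, camera adjusted p = 3.18e-34). Of 30 type I interferon genes 4 rose (4 adjusted over the list alone, camera adjusted p = 0.00419, and adjusted p = 0.563 with an estimated correlation). Of 18 plasma cell genes 2 rose, Ighm by 5.12 ± 0.61 (1.91 to 2.25 at its other probe sets) and the antibody joining chain Jchain by 1.86 ± 0.44 (3 up and 1 down adjusted over the list alone, camera adjusted p = 0.00993, and adjusted p = 0.168 with an estimated correlation). Alveolar macrophage genes fell in 4 of 14 cases (7 adjusted over the list alone, camera adjusted p = 0.000812, and adjusted p = 0.309 with an estimated correlation), among them Fabp1, which fell by 1.01 ± 0.27, and the scavenger receptor Marco, which fell by 0.96 ± 0.19. Heat shock genes rose in 4 of 8 cases (4 adjusted over the list alone, camera adjusted p = 0.000522, and adjusted p = 0.238 with an estimated correlation), with Hspa1a and Hsph1 up by 1.24 ± 0.41 and 0.68 ± 0.11. The call of Hspa1a ended without any of 10 single arrays of the 14. The count of 877 lay between 626 and 829 when any 1 array was left out, and was 1785 when only the arrays of these groups were fitted.

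At 70 d (n = 6 and 6), the last time, 134 genes were higher and 12 lower. Gzmk rose by 3.90 ± 0.23, a fold of 14.9, Cxcl9 by 3.10 ± 0.40 (1.23 at its second probe set), Cd8b1 by 2.29 ± 0.28, Cd8a by 2.12 ± 0.23, Klrg1 by 1.78 ± 0.20 and Ifng by 1.67 ± 0.22. Gzmk, Cxcl9 and Cd8a were each higher in 6 of 6 infected lungs than in any vehicle lung. Ighm rose by 4.66 ± 0.66 and gave 2.26 to 3.01 at its other probe sets, of which the lowest did not pass. All 15 T cell genes rose (15 adjusted over the list alone, camera adjusted p = 1.24e-64), as did 13 of 20 cytotoxic effector genes (14 adjusted over the list alone, camera adjusted p = 1.39e-59) and 4 of 21 interferon gamma genes (12 adjusted over the list alone, camera adjusted p = 5.46e-21). Of 18 plasma cell genes 1 rose (4 adjusted over the list alone, camera adjusted p = 3.75e-05). Of 25 cell cycle genes 2 rose (3 adjusted over the list alone, camera adjusted p = 1.35e-06, and adjusted p = 0.274 with an estimated correlation). The liver score was 6.45 ± 1.20 (SD) in infected and 5.52 ± 0.08 in vehicle lungs, an exact permutation p of 0.00216 and adjusted p of 0.027. The count of 146 was 85 without MHV_70d replicate 2 and 53 without the third of genes of lowest mean.

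Across the 10 times, 8009 genes (62%) differed between infected and vehicle lungs at some time in a limma F test. The largest F values were those of Gzmk (F = 292), Ifng (F = 167), Cxcl11 (F = 144), Cxcr6 (F = 131) and Il18bp (F = 131), a secreted inhibitor of interleukin 18. The size of the difference depended on time in 6338 genes (49.1%), again led by Gzmk (F = 137), Cxcl11 (F = 85.6) and Ifng (F = 76.5). From 4 d to 7 d the difference itself changed in 2737 genes and from 7 d to 14 d in 1833, and from 49 d to 70 d in 0 genes by limma. For the lists, tests of these successive differences were chosen after the data were seen. Between 7 d and 14 d the infection effect grew in 14 of 15 T cell genes (camera adjusted p = 2.77e-21 and adjusted p = 0.0294 with an estimated correlation). Over the same interval it shrank in 14 of 30 type I interferon genes (camera adjusted p = 2.38e-15, and adjusted p = 0.119 with an estimated correlation). Between 21 d and 35 d it shrank in 19 of 25 cell cycle genes (camera adjusted p = 1.36e-23) and in 13 of 21 interferon gamma genes (camera adjusted p = 9.62e-19), with adjusted p = 0.0225 and 0.0359 with an estimated correlation.

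The genes that passed at different times overlapped. The group means of these comparisons share no arrays, but all of them use the same estimate of each gene's spread. A gene with a small spread passes more easily at every time, so some sharing above that of independent lists can come from this. Of the 114 genes higher at 4 d, 101 were also higher at 7 d, where 15.5 would be shared by independent lists. Of the 134 genes higher at 70 d, 121 were higher at 14 d (20.6 for independent lists), 127 at 35 d (14 for independent lists) and 72 at 7 d (18.2 for independent lists). Between 7 d and 14 d, 987 higher genes were shared (269.9 for independent lists) and 1289 lower genes (667 for independent lists). Some pairs of times shared no more than independent lists would. The 6 h and 21 d comparisons shared 10 higher genes (12.9 for independent lists), and those at 4 d and 21 d shared 1 lower gene (2.4 for independent lists).

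Vehicle lungs also differed among themselves with time, in 7626 genes (59%) in the F test, and clock genes led them: Arntl (F = 52.1), Npas2 (F = 47.5) and Dbp (F = 42.3), with Sphk2 (F = 46.8) and Tmem171 (F = 46) between. Arntl, the activator of the circadian clock, was lowest at 6 h at 8.25 ± 0.35 (SD, n = 8) and highest at 21 d at 10.69 ± 0.24 (n = 8). Dbp, a clock output gene, went the other way, from 12.46 ± 0.15 at 6 h to 10.22 ± 0.77 at 21 d. Mean scores of other tissues differed between vehicle groups too, such as adipose tissue (9.92 at 6 h, 7.84 at 4 d) and liver (9.86 at 35 d, 6.01 at 49 d). How much of the 7626 genes this or the clock accounts for was not tested. Infected and vehicle lungs are compared within a time here, so that this variation enters a comparison only where treatments differ in it.

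**Figure D5:**
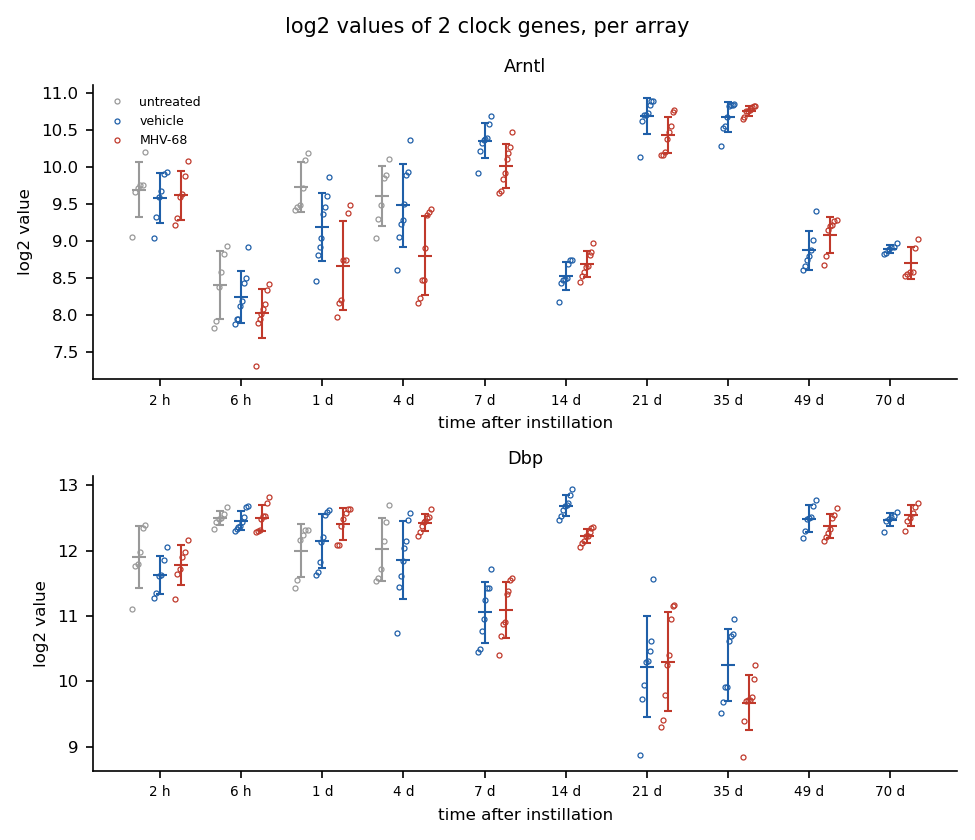
Points are log2 values of Arntl and Dbp on single arrays at each time after instillation, with the group mean and SD, for untreated, vehicle and infected lungs. In vehicle lungs Arntl is 10.69 at 21 d and 8.53 at 14 d on average, while Dbp is 10.22 and 12.69.

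The comparison of vehicle with untreated lungs asks what differed after the instillation itself. At 2 h (n = 6 and 6), the neutrophil chemokines Cxcl2 and Cxcl3 rose by 3.39 ± 0.49 (a fold of 10.5, in 6 of 6 vehicle lungs above any untreated lung) and 3.0 ± 0.39, Ccl20 by 1.69 ± 0.21 and Cxcl5 by 1.54 ± 0.19. Of 20 inflammatory genes 10 rose (11 adjusted over the list alone, camera adjusted p = 1.54e-14). Glucocorticoid-responsive genes rose in 5 of 17 cases (9 adjusted over the list alone, camera adjusted p = 5.93e-08, and adjusted p = 0.253 with an estimated correlation), with Zbtb16 and Fkbp5 up by 1.33 ± 0.35 and 1.32 ± 0.21. Cardiac muscle genes fell in 2 of 15 cases, Pln, which fell by 0.93 ± 0.28, and Tnni3, which fell by 0.73 ± 0.22 (9 adjusted over the list alone, camera adjusted p = 0.000117, and adjusted p = 0.807 with an estimated correlation). Mybpc3 and Corin, also genes of heart, fell by 1.16 ± 0.31 and 1.04 ± 0.29. With scores of other tissues as covariates, cardiac muscle among them, Pln, Tnni3, Mybpc3 and Corin were at -0.18, -0.11, -0.40 and -0.32 and Zbtb16 at 1.15, and none of them passed. The cardiac score holds Pln and Tnni3 themselves, so their smaller values with it are not independent evidence. The calls of Pln, Tnni3, Mybpc3, Corin and Zbtb16 also ended without some single arrays, and Corin was at -0.59 without Untreated_2h replicate 6. In all 179 genes were higher and 272 lower, or 53 and 54 with a fold of at least 1.5 as well. The 451 became 93 without Untreated_2h replicate 4, 1624 without Untreated_2h replicate 2, and 70 with scores of other tissues as covariates.

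At 6 h (n = 8 and 6), 8 genes were higher in vehicle than in untreated lungs and 1 lower. Cxcl3 rose by 3.52 ± 0.36, a fold of 11.5, in 8 of 8 vehicle lungs above any untreated lung, Cxcl2 by 2.72 ± 0.46, Saa3 by 1.39 ± 0.28 and Slc26a4 by 1.08 ± 0.22. Of 20 inflammatory genes 4 rose (10 adjusted over the list alone, camera adjusted p = 1.3e-11, and adjusted p = 0.0777 with an estimated correlation). At 1 d (n = 8 and 6), Saa3 rose by 1.28 ± 0.28 and the clock genes Per2 and Cry1 by 0.84 ± 0.20 and 0.50 ± 0.12, with Per2 at 0.16 to 0.36 and not passing at its other probe sets. Immediate early genes fell in 5 of 17 cases (11 adjusted over the list alone, camera adjusted p = 9.36e-10, and adjusted p = 0.667 with an estimated correlation), and Nr4a1 and Ier2 fell by 0.96 ± 0.26 and 0.62 ± 0.13. The 110 genes at 1 d, 38 higher and 72 lower, became 2 without Untreated_1d replicate 1 and 808 without Control_Prep_1d replicate 4. The calls of Saa3, Per2, Cry1, Nr4a1 and Ier2 all ended without Untreated_1d replicate 1. At 4 d (n = 8 and 6), no gene passed with limma, and 721 had an unadjusted p under 0.05. At that time 20 lists were called with the preset correlation, led by type I interferon genes (camera adjusted p = 1.45e-12, and adjusted p = 0.353 with an estimated correlation). No list was called there with an estimated correlation. None of the 30 type I interferon genes passed over all genes or over the list alone.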

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

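The tests of the 3 patterns weighed here, their criteria and the lists of liver, squamous epithelium and skeletal muscle genes were chosen or revised after the results were seen, while the splits of the samples were planned.

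Genes of liver stood lower in infected than in vehicle lungs at 35 d. Against an effect of infection on transcripts that vehicle lungs express throughout, the vehicle median of the liver score at 35 d lay at least 4.32 above those at 14 d, 49 d and 70 d. The vehicle lungs of 21 d did not enter that comparison, and their median was 7.20, with a highest value of 11.05. In infected lungs the median was 7.03 at 35 d and 5.49 at 49 d, so raised scores were not confined to vehicle lungs at 35 d. A candidate explanation is liver tissue in some samples: 19 genes of a second liver list had a median correlation of 0.91 with the score over the 32 arrays of 21 d and 35 d, group means taken out. At a mean above 9 in vehicle lungs at 49 d, lung expressed 0 of 12 genes of the first list and 5 of 19 of the second, and Alb, chosen after its values were seen, was 11.26 in vehicle lungs at 35 d and 7.18 at 49 d. Why the score differed between treatments at 35 d was not tested, and an infection effect at that time alone stays open.

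The changes at 6 h included genes of squamous epithelium and skeletal muscle. Other tissue in some samples is a candidate explanation for the 107 higher genes, of which 56.1% correlated above 0.5 in size with a squamous, skeletal muscle, cardiac, adipose or liver score over the 40 arrays of 2 h and 6 h, against 9.2% of genes not called. The squamous and skeletal muscle scores alone gave 30.8%. With the 5 scores as covariates 28 of the 107 stayed called, and the median of the 107 went from 0.54 (quartiles 0.38 and 0.82) to 0.41 (0.29 and 0.54). For the 109 lower genes other tissue cannot be told apart from infection: the share with any of the 5 scores was 3.7%, but 33% over the 22 arrays of 6 h alone (21.5% of genes not called, and 63.6% of the higher genes), and with the 5 scores as covariates 29 stayed called, while the median of the 109 went from -0.28 (quartiles -0.38 and -0.21) to -0.26 (-0.35 and -0.20). All 107 higher and all 109 lower genes kept an unadjusted limma p under 0.05 with the scores. A single array may decide most of the calls: 8.3% of the 216 genes passed in the same direction without MHV_6h replicate 2. An early response to the virus stays open, and chance was not excluded for this count (8 of 100 splits).

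Clock genes changed at 4 d. A different time of day at sacrifice is a candidate explanation. Over 16 clock genes the change correlated with the difference between vehicle animals at 14 d and 21 d, which are other arrays (Pearson's r 0.93, Spearman's rho 0.77, across genes, which are not independent replicates). Any joint shift of the clock genes could give such a correlation, so it does not favour time of day over an effect of infection on the clock at 4 d. A glucocorticoid response cannot be told apart, since 16 such genes had a camera p of 0.15 and a median of -0.02, with 2 that rose. A lasting effect of infection on the clock cannot be told apart either, since the correlation was 0.85 at 1 d and 0.23 at 7 d. The time of day is not given in the sources used here.

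Splits of the arrays of both groups into groups of the same sizes, 100 with the real one, asked whether chance can be excluded for each count. Chance was excluded for infected against vehicle lungs at 4 d (132 genes, highest other 104, 1 split as large), 7 d (4770, highest other 1837, 1 split), 14 d (4845, highest other 1160, 1 split), 21 d (3312, highest other 1196, 1 split), 35 d (3215, highest other 241, 1 split) and 49 d (877, highest other 227, 1 split). At 70 d (146, highest other 977) 3 splits were as large, without adjustment over the tests, so chance was not clearly excluded there. For vehicle against untreated lungs at 1 d (110, highest other 32) 1 split was as large, again without adjustment. That count of genes depended strongly on single arrays, so chance was not clearly excluded there either. With labels reassigned, chance was excluded for the F tests of any effect (8009, highest other 850, 1), of a change between times (6338, highest other 889, 1) and of vehicle lungs (7626, highest other 429, 1). It was not excluded for infected against vehicle lungs at 2 h (57, highest other 1635, 9 splits) and 6 h (216, highest other 1266, 8 splits), nor for vehicle against untreated lungs at 2 h (451, highest other 3542, 13 splits) and 6 h (9, highest other 444, 13 splits). In these 4 comparisons and for infected against vehicle lungs at 70 d a split called several times the real count. The arrays there thus also varied in ways other than treatment, and the reason was not tested. Where no gene passed, for infected against vehicle lungs at 1 d (highest other 2534) and vehicle against untreated lungs at 4 d (highest other 1386), all 100 splits call at least as many genes by construction, so the splits decide nothing there.

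Single arrays stood apart from their group in 35 of 240 tests of 10 measures in 24 groups, and chance flags about 1 in 20 groups. The actin 3' to 5' difference was highest in MHV_6h replicate 2 (2.07), MHV_2h replicate 3 (1.66), Control_Prep_70d replicate 3 (2.17), MHV_1d replicate 1 (1.47) and MHV_70d replicate 2 (2.33). The liver score was highest in MHV_49d replicate 3 (6.5), Control_Prep_49d replicate 2 (7.87), Control_Prep_14d replicate 3 (6.83), Control_Prep_4d replicate 1 (7.83), MHV_1d replicate 4 (6.80), MHV_14d replicate 2 (8.54) and Control_Prep_7d replicate 5 (7.99). The squamous score was highest in MHV_49d replicate 6 (6.53) and Control_Prep_49d replicate 7 (6.90). The skeletal muscle score was highest in Control_Prep_21d replicate 4 (11.35), Control_Prep_14d replicate 7 (8.70), MHV_4d replicate 1 (8.26), Control_Prep_4d replicate 4 (7.47) and MHV_14d replicate 1 (10.36). The cardiac score was lowest in Control_Prep_70d replicate 5 (9.21) and highest in Untreated_4d replicate 4 (11.54).

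Type I interferon genes were lowest in MHV_6h replicate 2 (10.18) and MHV_4d replicate 5 (9.95) and highest in Control_Prep_6h replicate 4 (10.55). Interferon gamma genes were lowest in MHV_6h replicate 2 (8.57) and highest in Control_Prep_14d replicate 5 (10.10). Cytotoxic effector genes were lowest in MHV_6h replicate 2 (6.98), MHV_4d replicate 5 (7.69) and MHV_70d replicate 1 (9.43) and highest in Control_Prep_35d replicate 3 (9.04). B cell genes were lowest in MHV_2h replicate 6 (8.95) and MHV_4d replicate 5 (8.55), and cell cycle genes in Control_Prep_49d replicate 1 (7.77), MHV_4d replicate 5 (7.49) and Untreated_4d replicate 2 (7.50).

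The infection effect differed between times in 6338 genes in the F test. Between successive times it differed in 61 genes (2 h to 6 h), 763 (6 h to 1 d), 48 (1 d to 4 d), 2737 (4 d to 7 d), 1833 (7 d to 14 d), 243 (14 d to 21 d), 678 (21 d to 35 d) and 94 (35 d to 49 d). Of the 2886 probe sets without a gene name, which the comparisons of genes do not use, 937 differed between infected and vehicle lungs at 7 d, 243 higher and 694 lower.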

How the results depend on the processing

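The settings with arrays of doubtful RNA left out, with scores of other tissues and with a clock component were chosen after the data were seen, and the others were planned. No paired analysis was possible because the labels give no replicate numbers. All 17 counts stayed within 1.5 times under eBayes with trend and robust settings, the mean of the probe sets of a gene and median centring. The count of genes at 7 d stayed within 1.5 times under each setting except the minimum fold. Below, I is infected minus vehicle and V is vehicle minus untreated, counts are of genes, and the cause was not tested except where a setting tests fewer genes or arrays. Small changes of dim genes are limited by the array's signal over background. Of the log2 changes of genes given with an SE, 153 stayed on their side of the threshold and 2 lost their call with quantile normalization, and 152 stayed and 3 lost it with median centring (Per3 and Scgb1a1 in both, Tef in the latter). With untreated animals as comparator 22 stayed, 13 lost their call, 1 gained it (Saa3 at 1 d) and Irf7 at 1 d, not called, turned to -0.07. With scores of other tissues 134 stayed and 18 lost their call, and at 35 d Cyp3a11, Mug1 and Serpina1c, which the liver score holds, turned to 1.18, 0.1 and 0.77. With single arrays left out 2151 values stayed, 188 lost their call and 6 gained it, and Irf7 at 1 d ranged from -0.01 (without Control_Prep_1d replicate 7) to 0.1. At other probe sets of these genes 54 values stayed on that side and 19 lost the call, those of Ighm, Arhgap28, Ccr2, Npas2, Per3, Tap1, Cxcl1, Rsad2, Per2 and Zbtb16.

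Without the third of genes with the lowest mean, which tests fewer genes, the counts were I 34 at 2 h, 102 at 6 h, 2161 at 21 d, 507 at 49 d and 53 at 70 d, and V 239 at 2 h and 1 at 6 h. Quantile normalization gave I 404 at 6 h and V 167 at 1 d, and all probe sets V 246 at 1 d. Array weights gave I 357 at 2 h, 104 at 6 h, 1432 at 1 d, 228 at 4 d, 8010 at 14 d, 7542 at 35 d, 2783 at 49 d and 312 at 70 d, V 296 at 2 h, 269 at 6 h and 800 at 1 d, and 10727 in the F test of a change between times. An RNA quality covariate gave I 87 at 2 h and 78 at 6 h, and V 145 at 2 h, 14 at 6 h and 4 at 1 d. The first residual component as a covariate gave I 224 at 2 h, 2115 at 6 h, 2258 at 1 d, 202 at 4 d, 5055 at 35 d, 1656 at 49 d and 308 at 70 d, V 3259 at 2 h, 242 at 6 h, 2280 at 1 d and 384 at 4 d, and 9689 in that F test. A fold of at least 1.5 gave I 24 at 2 h, 51 at 6 h, 59 at 4 d, 661 at 7 d, 938 at 14 d, 741 at 21 d, 414 at 35 d, 191 at 49 d and 77 at 70 d, and V 107 at 2 h, 5 at 6 h and 12 at 1 d. Only the arrays of the 2 groups gave I 2 at 2 h, 1 at 6 h, 47 at 4 d, 5430 at 35 d, 1785 at 49 d and 84 at 70 d, and V 17 at 2 h, 29 at 6 h and 41 at 1 d. Untreated animals as comparator gave 462 at 2 h, 491 at 6 h and 32 at 1 d. Without arrays of doubtful RNA (9 arrays above 1.65) the counts were I 95 at 2 h, 21 at 6 h and 151 at 1 d, and V 29 at 6 h, 456 at 1 d and 1 at 4 d. Scores of other tissues gave I 55 at 6 h and V 70 at 2 h, 19 at 6 h and 52 at 1 d, and a clock component I 24 at 1 d and V 38 at 1 d.

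With an estimated correlation the numbers of lists called were I 0 (against 4) at 2 h, 0 (12) at 6 h, 0 (6) at 1 d, 4 (13) at 4 d, 9 (19) at 7 d, 13 (23) at 14 d, 7 (17) at 35 d, 6 (25) at 49 d and 8 (17) at 70 d, and V 1 (6) at 2 h, 0 (5) at 6 h, 0 (8) at 1 d and 0 (20) at 4 d. Without the third of genes with the lowest mean they were I 3 at 1 d and V 2 at 6 h and 4 at 1 d.

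With each array left out in turn the counts were I 22 to 83 at 2 h, 20 to 861 at 6 h, 0 to 23 at 1 d, 106 to 144 at 4 d, 4170 to 4940 at 7 d, 4390 to 4801 at 14 d, 2727 to 3369 at 21 d, 2532 to 3622 at 35 d, 626 to 829 at 49 d and 85 to 181 at 70 d, and V 93 to 1624 at 2 h, 5 to 12 at 6 h, 2 to 808 at 1 d and 0 at 4 d. Arrays that moved a count by over 1.5 times were, for I at 2 h, MHV_2h replicates 1 (24) and 5 (22) and Control_Prep_2h replicates 1 (36), 5 (31) and 6 (32). For I at 6 h they were MHV_6h replicates 2 (20), 3 (861), 5 (707), 6 (364), 7 (355) and 8 (408) and Control_Prep_6h replicates 3 (327), 4 (36), 5 (91), 6 (124), 7 (140) and 8 (61). For I at 1 d they were MHV_1d replicates 1 (23), 3 (1), 4 (1) and 5 (1) and Control_Prep_1d replicates 2 (1), 3 (5), 4 (15), 5 (1) and 6 (2), and at 70 d MHV_70d replicate 2 (85). For V at 2 h they were Untreated_2h replicates 1 (783), 2 (1624), 3 (861), 4 (93) and 5 (120) and Control_Prep_2h replicates 1 (257), 4 (815), 5 (135) and 6 (123). For V at 6 h they were Control_Prep_6h replicate 6 (5) and Untreated_6h replicate 4 (5). For V at 1 d they were Control_Prep_1d replicates 1 (3), 2 (242), 3 (51), 4 (808), 5 (250), 6 (307), 7 (3) and 8 (33) and Untreated_1d replicates 1 (2), 2 (17), 3 (16), 4 (28), 5 (53) and 6 (233).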

Other observations

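The genes singled out in this part were chosen after the data were seen, and no explanation was tested for them.

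Between 14 d and 70 d, 116 genes differed between infected and vehicle lungs at each of the 5 times in the same direction, 114 higher and 2 lower. The higher ones included the components Cd3d, Cd3e and Cd3g of the T cell receptor complex, the coreceptors Cd4, Cd8a and Cd8b1, and the receptor signalling genes Zap70, Lat and Themis. They also included the transcription factors Tbx21, Eomes, Runx3 and Stat4 of effector lymphocytes, the chemokine receptors Cxcr3 and Cxcr6, and Cxcl9, Cxcl10 and Cxcl11, which encode ligands of Cxcr3. Itgae, an integrin of T cells and dendritic cells in epithelia, Xcr1, a receptor of dendritic cells that cross-present antigen, and the complement gene C1qc were among them. The lower ones were Mccc1 and Pafah2. Of the 116 genes, 70 differed at 7 d as well in the same direction.

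Of the 8574 genes that differed at any time, the largest difference fell at 7 d in 2738 and at 14 d in 2851. It fell at 21 d in 1326, at 35 d in 1266, at 49 d in 208 and at 70 d in 15.

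Genes of adipose tissue stood high at 2 h and 6 h in every treatment. At 6 h their score was 10.19 ± 0.84 (SD, n = 8) in infected, 9.92 ± 0.76 (n = 8) in vehicle and 10.29 ± 0.68 (n = 6) in untreated lungs, and at 4 d 7.89 ± 0.16 (n = 8), 7.84 ± 0.29 (n = 8) and 7.96 ± 0.37 (n = 6). The difference between times was not tested.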
